A study of Rattus norvegicus with 43 samples.

How the data were processed

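RNA from the distal colon of 11-week-old Sprague Dawley rats was hybridised to Affymetrix arrays, starting from 100 ng of total RNA per animal. The 43 arrays fall into 6 diets, and each array comes from a different rat. The labels give the diets as codes; their reading as control, low- and high-amylose maize starch, butyrylated high-amylose maize starch, and low- and high-amylose wheat rests on what is known of the study, as does taking LAMS as the Western diet with low-amylose starch. The label HAM was read as HAMS, the name the series description uses. The deposited table holds log2 expression values for 29214 probe sets, which the authors made with RMA per the submitters' processing notes. RMA, the only tool named there, corrects background, brings the arrays to a shared distribution and summarises probes into probe sets; its version was not given. The values ran from 1.31 to 14.05. Raw array images were not analysed here.

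Of the probe sets, 15310 were listed with 1 gene symbol, 323 with several and 13581 with none. The tested set held 1 probe set per symbol, the one with the highest mean over all arrays, among the probe sets with exactly 1 symbol. A probe set was kept when its median over all arrays reached the 25th percentile of the probe sets with a symbol, 4.75 on the log2 scale. From 14506 symbols this left 10934 genes. Arrays carry no read depth; the number of animals and the signal over background limit the precision.

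A linear model with a mean for each of the 6 diets was fitted to every gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior). The comparisons were LAMS minus CON, HAMS minus LAMS, HAMSB minus LAMS, HAMSB minus HAMS, HAW minus LAW, LAW minus LAMS, the mean of both wheats minus the mean of LAMS and HAMS, and the amylose effect in wheat minus that in maize, together with a moderated F test over the 6 diets. Tests were two-sided, adjusted by the method of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. These settings, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

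The 37 gene lists, of pathways and of cell types, held 881 members, of which 669 were tested, 11 of them matched through older names. The 36 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists within a comparison. Beside it stand the counts of members past the threshold over all genes and adjusted over the list alone, camera with a correlation estimated from the data, and fry, which asks whether the genes of a list move on balance in 1 direction. None of the list calls held with the estimated correlation. With fry 1 list passed in LAMS minus CON, 8 in HAMS minus LAMS, 17 in HAMSB minus HAMS and 0 in each of the other 5 comparisons. Where a list passed, its median, its mean and its test had the same sign.

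The rule for named genes took, per comparison, the 8 largest rises and the 8 largest falls among the genes that passed, or the 10 genes with the smallest p where fewer than 10 passed. It added up to 4 members with the smallest p from each list that passed or held a changed gene, and 8 genes fixed for every comparison, 1 of which is not reported here. All genes of the first kind are named in the text. The list members that are named are a choice made after their values were seen, since the rule took up to 145 genes in a comparison. The fixed genes that did not pass are given as ranges.

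Alternatives for the counts were no filter on low signal, a stricter filter, all probe sets, a trended and robust prior, array weights, a fit of the compared diets alone, centring of each array, and blocks by the style of the array file names, by the range of the animal numbers, by both, and by replicate number, and leaving out each array in turn. The trended and robust prior could be applied to the list tests only as a trend of the variance, since camera has no robust prior. Array spread and the lymphoid level as covariates, name style together with the lymphoid level, leaving out the 2 arrays of lowest spread, and restriction to 1 name style, also for the array spread and the lymphoid level, were chosen after seeing the data. The mean of the B cell and germinal centre list on each array is called the lymphoid level.

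Opposition to the LAMS minus CON difference was measured as the covariance and correlation over genes with each starch effect, averaged over all divisions of the LAMS arrays into parts that share no array. It was set against 100 permutations of the model's residuals over the arrays, which stand for unchanged diets. A first version of that permutation did not refit the block and did not rescale the residuals, and its values with name style as a block lay below 0.05; it was corrected after those values had been seen, and only the corrected values are given. Other splits of the arrays were drawn 100 times per comparison, the real split included; they were drawn anew, to exclude duplicates, after a first draw had been seen. Comparisons of 1 value per array used exact permutation tests. The share of a change that name style, array spread or the lymphoid level predicts was computed from slopes fitted within diets outside the comparison. Its 95% interval came from 100 resamplings of the arrays within those outside diets (92 for name style in HAMSB minus HAMS, since the other 8 could not be fitted). The change and the difference in level between the compared diets were held fixed, so the interval leaves out their sampling error.

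The procedure was tested on simulated data, drawn for each gene from a normal distribution with its mean and residual SD and with no correlation between genes, with 100 genes planted at a difference of 0.5 and 100 at a difference of 1. At 0.5, recovery was 52% in LAMS minus CON, 50% in HAMS minus LAMS, 64% in HAMSB minus LAMS and 69% in HAMSB minus HAMS. It was 53% in HAW minus LAW, 55% in LAW minus LAMS, 86% in wheat minus maize and 22% for the difference of amylose effects. At 1, recovery ran from 82% to 99%. False calls numbered 4 to 14 per comparison, 3.14% to 8.75% of the calls, and with no change planted 0 genes were called. A planted list passed, with 1 other list passing. In the data genes moved together, with 5796 of 10934 following the lymphoid level. The simulation therefore does not show how many false calls such shared shifts make, nor whether the preset correlation of the list test is adequate. A planted share of 0% was estimated at 0.679% and a planted share of 100% at 97.4%. The planted genes were given to that estimate directly, so the check does not cover the picking of genes by their p. A planted covariance of -0.04 was estimated at -0.0383.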

Results

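Gene expression was measured with Affymetrix arrays in the distal colon of Sprague Dawley rats fed 1 of 6 diets. The 43 arrays, each from a different animal, comprised a control diet (CON, n = 5), low-amylose maize starch (LAMS, n = 7), high-amylose maize starch (HAMS, n = 8), butyrylated high-amylose maize starch (HAMSB, n = 9), low-amylose wheat (LAW, n = 6) and high-amylose wheat (HAW, n = 8). High-amylose starches resist digestion in the small intestine, and butyrylated starch carries esterified butyrate into the large bowel. All values below are on the log2 scale, differences are given ± their standard error from limma, diet means ± SD, and 10934 genes were tested. The number of arrays limits the precision: the median 95% interval of a gene reached 0.25 to either side in HAMS minus LAMS and 0.36 in the comparison of the amylose effects of wheat and maize. Diet changed 3355 genes in the F test over all 6 diets.

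Genes of B cells and germinal centres, a list fixed beforehand, varied among animals within diets. Their mean level was 7.76 ± 1.33 in HAMS (n = 8), 6.59 ± 1.23 in LAMS (n = 7) and 6.52 ± 0.99 in HAMSB (n = 9). The exact two-sided permutation test gave p = 0.1 for HAMS minus LAMS (0.3 after adjustment over 6 comparisons) and p = 0.0474 for HAMSB minus HAMS (0.284 adjusted). Within the 1 style of file names that all HAMS arrays share, the differences were 2.08 (8 against 3 arrays, exact permutation p = 0.0424, 0.127 adjusted) and -1.66 (5 against 8, p = 0.0287, 0.127 adjusted). The spread of all values within an array, its interquartile range, was 3.01 ± 0.14 in HAMS, 3.21 ± 0.09 in LAMS and 3.12 ± 0.08 in HAMSB. HAMS arrays were narrower than LAMS arrays by the exact permutation test (p = 0.00435, 0.0261 adjusted over 6), and than HAMSB arrays before adjustment (p = 0.0323, 0.0969 adjusted). Within that name style HAMS minus LAMS was -0.12 in place of -0.20 (exact permutation p = 0.212, 0.558 adjusted) and HAMSB minus HAMS 0.08 in place of 0.12 (p = 0.279, 0.558 adjusted). With diet in the model, 5796 genes followed the lymphoid level, 5569 followed the spread and 4666 followed the style in which the array file names were written, a batch-like mark in the labels. All 8 HAMS arrays shared 1 name style with 3 LAMS and 5 HAMSB arrays, so the total of changed genes in each comparison is also given with name style as a block. With that block, diet changed 1398 genes, of which 1020 were among the 3355.

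**Figure D1:**
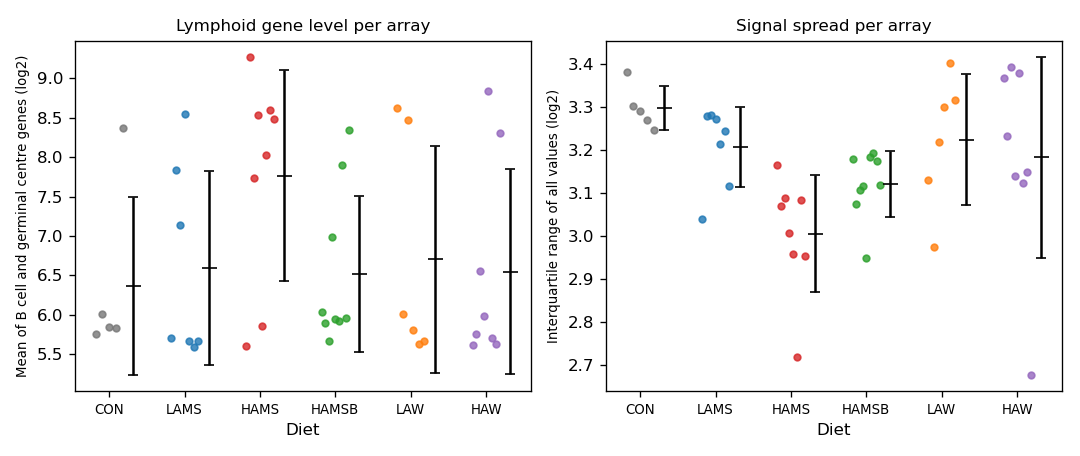
Each point is an array, placed by diet; the left axis is the mean log2 level of the B cell and germinal centre genes and the right axis the interquartile range of all log2 values of the array, with bars for the mean ± SD. HAMS had the highest mean lymphoid level (7.76) and the lowest mean spread (3.01).

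The comparison of LAMS with CON asked what the Western-type low-amylose diet did to the colon. No gene passed with limma, and 938 had an unadjusted p under 0.05. The 10 genes with the smallest p all lay lower in LAMS (n = 7) than in CON (n = 5), each with an adjusted p of 0.0769. The lowest was Cspg5, a chondroitin sulphate proteoglycan of neural tissue, at -0.72 ± 0.14 (4.58 ± 0.32 in LAMS, under the low-signal floor of 4.75 that the filter used, against 5.30 ± 0.15 in CON). Ret, the receptor kinase needed for enteric nervous system development, was at -0.61 ± 0.13, Rai2 at -0.59 ± 0.13, and the synaptic adhesion gene Nlgn2 at -0.47 ± 0.10. Vstm4, Steap4, Hs3st1, Nabp2, Tesk1 and Pear1 lay between -0.48 and -0.38.

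In LAMS minus CON, 7 of 36 gene lists passed the list test with a preset correlation, 3 upward and 4 downward. The list of enteric neurons and glia was shifted down (median -0.35, adjusted p = 0.000256; adjusted p = 0.933 with an estimated correlation). None of its 17 genes passed over all genes, and 7 were lower when adjusted over the list alone, with Prph at -0.62 ± 0.22 and Uchl1 at -0.58 ± 0.20. Endothelial genes were also shifted down (median -0.22, adjusted p = 0.000235; adjusted p = 0.425 with an estimated correlation), with none of 16 past the test over all genes, 2 lower adjusted over the list alone, and Eng at -0.33 ± 0.10. Smooth muscle (median -0.21, adjusted p = 0.008) and enteroendocrine genes (median -0.20, adjusted p = 0.0125, Chga at -0.37 ± 0.12) followed, both with an adjusted p of 0.933 with an estimated correlation. Upward shifts were small for cholesterol synthesis (median 0.10, adjusted p = 0.00242, Lss at 0.42 ± 0.15), mismatch repair (median 0.10, adjusted p = 0.008) and fatty acid oxidation (median 0.07, adjusted p = 0.00652, Decr1 at 0.39 ± 0.17), each again with an adjusted p of 0.933 with an estimated correlation. None of the members of these 5 lists passed over all genes; adjusted over the list alone, 2 enteroendocrine genes were lower and 0 genes of the other lists passed. With name style as a block 36 genes passed, all lower in LAMS, among them Cspg5 (-0.84, adjusted p = 0.0224) and Chga (-0.52, adjusted p = 0.0433). Within the only name style shared by both diets, 4 LAMS arrays against 2 CON arrays gave 0 genes with limma. Of the lists, 9 passed with the block, 6 of them among the 7, and 1 with fry (endothelial genes, adjusted p = 0.0242). Array weights gave 234 genes, 224 of them lower.

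High-amylose against low-amylose maize starch (HAMS minus LAMS) addressed the effect of resistant starch in a maize diet. In HAMS (n = 8) against LAMS (n = 7), 1545 genes changed, of which 1308 fell and 237 rose. The largest fall was in Akr1c19, an aldo-keto reductase (-1.42 ± 0.23, adjusted p = 0.00182). Med14 of the Mediator complex fell by 1.38 ± 0.29 and Aspn, an extracellular matrix proteoglycan, by 1.35 ± 0.31. The HAMS means of Akr1c19 (4.19) and Med14 (4.45) lay under the low-signal floor of 4.75. Scin, Yes1, the cytokine gene Il18, the metalloprotease gene Adamdec1 and the tight junction gene Cldn8 each fell, with values between -1.06 and -1.05. The largest rise was in the protease inhibitor Slpi (1.55 ± 0.48, adjusted p = 0.0294), followed by Ccdc107 (1.33 ± 0.26) and Fancd2osl1 (1.29 ± 0.31). The lymphocyte genes Sit1 (1.02 ± 0.35) and Ptpn7 (0.86 ± 0.28) rose, as did Smap2 (0.97 ± 0.34), LOC366310 (0.96 ± 0.18) and Rpph1, the RNA component of ribonuclease P (0.89 ± 0.15). Leaving out 1 array at a time ended the calls of Sit1 in 10 of 15 runs (highest adjusted p = 0.107), Ptpn7 in 10 (0.0843), Smap2 in 11 (0.114) and Slpi in 7 (0.0776).

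Of 7 metabolic lists, those of fatty acid oxidation, sulphide handling and the xenobiotic response were shifted down in HAMS against LAMS, and 4 did not pass. Of 25 tested genes of fatty acid oxidation and ketogenesis, 7 fell, 0 rose and 18 did not pass, with 10 lower when adjusted over the list alone. Acaa2 (-0.65 ± 0.17) and Decr1 (-0.58 ± 0.15) were among them, and the list passed (median -0.34, adjusted p = 0.00649; adjusted p = 0.749 with an estimated correlation). In sulphide, ammonia and amino acid handling 7 of 18 fell and 11 did not pass, with 10 lower adjusted over the list alone. They included Cth, which makes cysteine and hydrogen sulphide (-0.92 ± 0.23), Sqor, which oxidises sulphide (-0.72 ± 0.18), and the urea cycle gene Asl (-0.31 ± 0.08), with a list median of -0.35 (adjusted p = 0.00141; adjusted p = 0.643 with an estimated correlation). Among 18 xenobiotic and oxidative stress genes 3 fell and 15 did not pass, with 5 lower adjusted over the list alone, as for Cyp3a9 (-0.68 ± 0.20; list adjusted p = 0.0278; adjusted p = 0.706 with an estimated correlation). Of 11 genes of short-chain fatty acid transport and sensing 2 fell, over all genes and adjusted over the list alone: Slc16a1, the butyrate transporter of colonocytes (-0.54 ± 0.15, adjusted p = 0.0198), and Acss2 (-0.49 ± 0.13). That list did not pass (adjusted p = 0.259). Of 34 oxidative phosphorylation genes 2 fell, including Ndufs1 (-0.53 ± 0.15), with 1 lower adjusted over the list alone and a list adjusted p of 0.0852. Of 19 cholesterol synthesis genes 0 passed and of 16 fatty acid synthesis genes 1 fell, with 0 in either list adjusted over the list alone, and both lists had an adjusted p of 0.955. Over the 43 arrays, within diets, these lists ran against the lymphoid level, which was higher by 1.17 in HAMS than in LAMS. The correlation was r = -0.84 for fatty acid oxidation, -0.88 for sulphide handling, -0.85 for the xenobiotic response, -0.85 for short-chain fatty acids and -0.81 for oxidative phosphorylation (-0.91 to -0.84 within diets and name styles), and -0.46 and -0.28 for cholesterol and fatty acid synthesis. The adjusted p of the first 5 was 0.021, 0.00151, 0.195, 0.828 and 9.72e-05 with name style as a block and the lymphoid level as a covariate.

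Lists of transport, secretory and stromal genes were also shifted down in HAMS against LAMS. Of 23 ion and water transport genes 6 fell and 17 did not pass, with 11 lower adjusted over the list alone. The chloride channel Cftr was at -0.73 ± 0.23 and the cotransporter Slc12a2 at -0.71 ± 0.18 (list median -0.46, adjusted p = 0.027; adjusted p = 0.752 with an estimated correlation). Of 19 goblet cell genes 6 fell and 13 did not pass, with 10 lower adjusted over the list alone. Agr2, needed for mucin folding, fell from 11.10 ± 0.49 to 10.32 ± 0.66 (-0.78 ± 0.22), and Creb3l4 was at -0.77 ± 0.19 (list median -0.31, adjusted p = 0.00524; adjusted p = 0.749 with an estimated correlation). Fibroblast and matrix genes showed 10 falls among 19 with 9 not passing, and 14 lower adjusted over the list alone. Decorin (Dcn, -0.87 ± 0.17), Lum (-0.74 ± 0.17) and the collagen gene Col3a1 (-0.70 ± 0.14) were among the falls (list median -0.48, adjusted p = 7.73e-06; adjusted p = 0.643 with an estimated correlation). Of 20 smooth muscle genes 7 fell and 13 did not pass, with 10 lower adjusted over the list alone (median -0.35, adjusted p = 0.00141; adjusted p = 0.749 with an estimated correlation). Of 15 adipocyte genes 2 fell, by either adjustment, including Pck1 (-0.99 ± 0.23; list adjusted p = 0.0497; adjusted p = 0.752 with an estimated correlation). These lists too ran against the lymphoid level within diets, with r = -0.77 for ion and water transport, -0.82 for goblet cells, -0.71 for fibroblasts, -0.67 for smooth muscle and -0.58 for adipocytes (-0.84 to -0.57 within diets and name styles). The calls of ion and water transport (adjusted p = 0.64), goblet cells (0.195) and smooth muscle (0.195) ended with name style as a block and the lymphoid level as a covariate, while fibroblasts (0.00382) and adipocytes (0.00936) passed.

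Lymphoid groups lay higher in HAMS than in LAMS, beside the higher mean lymphoid level of the HAMS arrays given above. The list medians were 1.31 for B cells and germinal centres (adjusted p = 2.78e-06), 0.80 for T and NK cells (adjusted p = 3.75e-05), 0.49 for MHC class II presentation (adjusted p = 0.00141) and 0.17 for plasma cells (adjusted p = 0.037). Each had an adjusted p of 0.643 with an estimated correlation. The lymphoid level is the mean of the first of these lists and followed the next 2 at r = 0.97 within diets, so adjusting these 3 for it decides nothing; the plasma cell list did not pass with name style as a block and the lymphoid level as a covariate (adjusted p = 0.195). None of the 16 B cell genes passed by either adjustment, as for Spib at 1.50 ± 0.61 (adjusted p = 0.0809). Of 17 T and NK cell genes, Thy1, which fibroblasts also express, fell (-0.51 ± 0.16), the other 16 did not pass, and 0 passed adjusted over the list alone. Of the 11 MHC class II genes 0 passed over all genes, while 3 were higher and 1 lower adjusted over the list alone. Of 42 ribosomal protein genes 5 rose, including Rpl35 (0.44 ± 0.12), with 3 higher adjusted over the list alone (median 0.09, adjusted p = 2.26e-06; adjusted p = 0.643 with an estimated correlation). With name style as a block that median was 0.01 (adjusted p = 0.0924). Among 14 mismatch repair genes 2 fell by either adjustment, Mlh3 (-0.55 ± 0.15) and Msh3 (-0.47 ± 0.13, adjusted p = 0.0155), and the list did not pass (adjusted p = 0.955).

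In HAMS minus LAMS, name style as a block left 945 genes, 687 lower and 258 higher, of which 442 were among the 1545. Within 1 name style (8 against 3 arrays) 1199 genes passed. There the lymphoid level differed by 2.08, against 1.17 over all arrays, so the restriction widened that difference. The block together with the lymphoid level as a covariate left far fewer genes than the block alone, as given under the dependence on processing. Calls for Msh3 (-0.27, adjusted p = 0.129), Mlh3 (adjusted p = 0.161), Slc16a1 (-0.51, adjusted p = 0.0512), Cftr (adjusted p = 0.143), Cyp3a9 (adjusted p = 0.136), Slc12a2 (adjusted p = 0.0641), Ndufs1 (adjusted p = 0.096), Rpl35 (adjusted p = 0.156), Aspn (adjusted p = 0.0546), Yes1 (adjusted p = 0.0979), Fancd2osl1 (adjusted p = 0.0948) and Ptpn7 (adjusted p = 0.0510) ended with the block, and array spread as a covariate left 6 genes and the lymphoid level as a covariate 575, while array weights gave 4059. Leaving out 1 array at a time gave 614 genes (without LAMS replicate 6) to 2425 (without HAMS replicate 1), and besides the 4 calls named above it ended those of Cftr in 7 of 15 runs (highest adjusted p = 0.0809), Cyp3a9 in 5 (0.0638), Rpl35 (0.0628) and Slc16a1 (0.0532) in 2 and Agr2 without HAMS replicate 2 (0.0518). Of 36 lists 13 passed, 15 with the block (11 of the 13), 8 with fry, and 5 with the block and the lymphoid level.

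**Figure D2:**
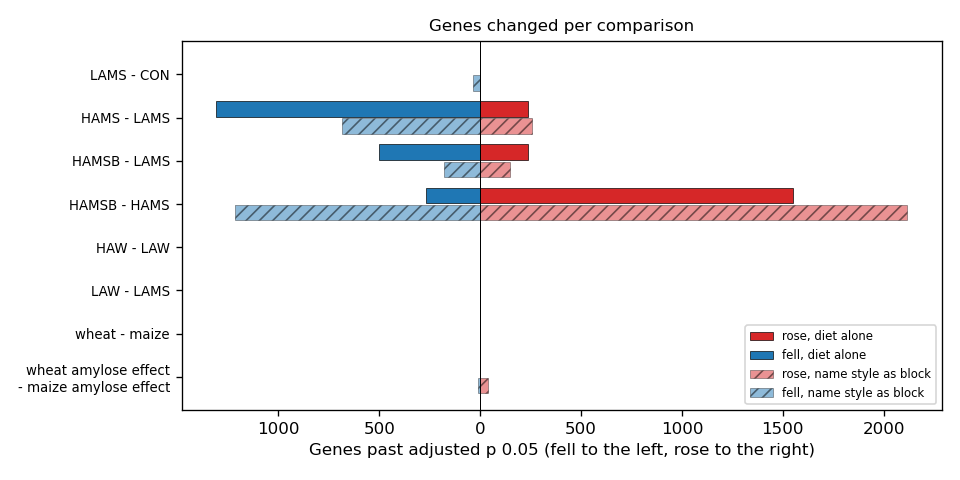
Horizontal bars count the genes past an adjusted p of 0.05 in each comparison, falls to the left and rises to the right, for the diet model and for the model with name style as a block. HAMSB minus HAMS holds the most genes, 1821 with diet alone and 3334 with the block.

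Butyrylated high-amylose starch against low-amylose starch (HAMSB minus LAMS) addressed the effect of delivering butyrate with resistant starch. In HAMSB (n = 9) against LAMS (n = 7), 741 genes changed, of which 502 fell and 239 rose. Guca2b, which encodes uroguanylin, an activator of intestinal fluid secretion, rose by 1.16 ± 0.21, from 8.01 ± 0.49 to 9.17 ± 0.31 (adjusted p = 0.00474). Jchain, the joining chain of secreted IgA and IgM, rose by 1.01 ± 0.26, and Cyp4b1, H4c14, Atp5mk, Cyp2d5, Cd7 and Gchfr rose by 0.70 to 0.82. The amino acid transporter gene Slc6a14 fell by 1.37 ± 0.26, from 8.89 ± 0.65 to 7.53 ± 0.64 (adjusted p = 0.00474), and Abcb1a, the drug efflux pump P-glycoprotein, fell by 1.20 ± 0.25. Med14 (-1.09 ± 0.28, with a HAMSB mean of 4.73 at the low-signal floor), Vsig1 (-0.97 ± 0.21), Yes1 (-0.94 ± 0.26), Prpf39 (-0.85 ± 0.22), Fbxl5 (-0.84 ± 0.15) and Zfp638 (-0.83 ± 0.20) also fell.

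DNA repair genes changed in both directions in HAMSB against LAMS. Of 22 genes of base excision and single-strand break repair 1 rose, 3 fell and 18 did not pass, with the same counts adjusted over the list alone. The uracil-DNA glycosylase gene Ung rose by 0.45 ± 0.11 (adjusted p = 0.0141), while the thymine-DNA glycosylase gene Tdg (-0.57 ± 0.11), the topoisomerase gene Top1 (-0.46 ± 0.13) and Parg, which removes poly(ADP-ribose) (-0.45 ± 0.11), fell. Mlh3 (-0.55 ± 0.14) and Msh3 (-0.51 ± 0.12, adjusted p = 0.0134) were the 2 falls among 14 mismatch repair genes by either adjustment. The ligase gene Lig4 (-0.72 ± 0.21) was the only fall among 16 double-strand break repair genes over all genes, with 4 lower adjusted over the list alone. None of these 3 lists passed its test (adjusted p = 0.644, 0.46 and 0.148).

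Heat shock genes were among the falls in HAMSB against LAMS: 3 of the 20 genes of the immediate early and heat shock list fell by either adjustment, Hsph1 (-0.69 ± 0.17), Hsp90aa1 (-0.64 ± 0.18) and Hspa8 (-0.52 ± 0.10). That list did not pass (adjusted p = 0.644). Chga, a granin of enteroendocrine cells, rose by 0.41 ± 0.10, 1 of 14 genes of its list, with 2 higher adjusted over the list alone. Odc1, of polyamine synthesis, fell by 0.54 ± 0.14. The endothelial genes Plvap (0.37 ± 0.10) and Eng (0.28 ± 0.09) were the 2 rises among 16 of their list by either adjustment. Oxidative phosphorylation (median 0.25) and ribosomal proteins (median 0.15) were the 2 lists that passed, each with an adjusted p of 0.0272 (adjusted p = 0.997 with an estimated correlation). Ndufb10 (0.51 ± 0.15) was the only rise among 34 oxidative phosphorylation genes, with 0 adjusted over the list alone. Rpl38 (0.61 ± 0.16) was 1 of 2 rises among 42 ribosomal genes, with 1 adjusted over the list alone.

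In HAMSB minus LAMS, name style as a block left 327 genes, 150 higher and 177 lower, of which 199 were among the 741, and 38 genes passed within 1 name style (5 against 3 arrays). The block kept the calls of Guca2b, Slc6a14, Abcb1a, Jchain, Ung, Tdg, Hspa8, Chga, Eng, Rpl38, Odc1, Atp5mk, Cyp2d5, Med14, Fbxl5 and Zfp638; it ended those of Msh3 (-0.38, adjusted p = 0.0803), Parg (-0.26, adjusted p = 0.0627), Top1 (-0.27, adjusted p = 0.128), Mlh3 (adjusted p = 0.0896), Lig4 (adjusted p = 0.181), Hsph1 (adjusted p = 0.0672), Hsp90aa1 (adjusted p = 0.2), Ndufb10 (adjusted p = 0.276), Plvap (adjusted p = 0.173), Cyp4b1 (adjusted p = 0.0896), H4c14 (adjusted p = 0.183), Cd7 (adjusted p = 0.08), Gchfr (adjusted p = 0.246), Vsig1 (adjusted p = 0.0578), Yes1 (adjusted p = 0.123) and Prpf39 (adjusted p = 0.0798), and of both lists. The block takes the style effect as equal in all diets. HAMSB replicates 6 to 9 bear another name style and higher animal numbers than replicates 1 to 5. Slc6a14 was at 7.77 to 8.40 in the former and 6.68 to 7.62 in the latter. Ung was at 7.29 to 7.72 and 7.68 to 8.21, Chga at 6.35 to 6.60 and 6.61 to 6.87, and Guca2b at 8.76 to 9.47 and 8.96 to 9.72. The kept calls are thus not shown to be free of the batch-like mark. Leaving out 1 array at a time gave 158 genes (without LAMS replicate 2) to 1384 (without LAMS replicate 1). It ended the calls of Eng (highest adjusted p = 0.129) and Cyp4b1 (0.132) in 10 of 16 runs, Atp5mk, H4c14, Lig4 and Ndufb10 in 9, Hsp90aa1 in 8, Top1 in 7 (0.0777), Yes1 in 6, Gchfr and Mlh3 in 5, Plvap in 4, Jchain (0.0694) and Med14 in 3, Odc1, Prpf39 and Rpl38 in 2, and Chga, Hsph1, Parg and Zfp638 without LAMS replicate 2. Array weights gave 3724 genes, and with fry 0 of 36 lists passed.

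Butyrylated against plain high-amylose starch (HAMSB minus HAMS) asked what the butyryl groups added. In HAMSB (n = 9) against HAMS (n = 8), 1821 genes changed, of which 1550 rose and 271 fell. The goblet cell gene Retnlb, encoding the resistin-like protein RELMβ, rose 8.34-fold (3.06 ± 0.58, adjusted p = 0.0013), from a mean of 6.17 to 9.23, against 9.18 in CON (n = 5), with SDs of 1.11 to 1.51. Its relatives Retnla (2.91 ± 0.57) and Retnlg (1.21 ± 0.30), the mucosal pentraxin gene Mptx1 (1.68 ± 0.39) and the lectin gene Itln1 (1.40 ± 0.31) rose too. The sodium-proton exchanger gene Slc9a3 (1.31 ± 0.39), Cmc1 (1.25 ± 0.24) and the fatty acid binding protein gene Fabp2 (1.18 ± 0.30, from a HAMS mean of 4.73 at the low-signal floor) completed the largest rises. The largest falls were lymphocyte genes: the chemokine receptor gene Cxcr4 (-2.13 ± 0.68, adjusted p = 0.0293), P2ry10 (-2.12 ± 0.69, to a HAMSB mean of 4.73, under the low-signal floor), the transcription factor genes Ikzf1 (-1.93 ± 0.65), Ikzf3 (-1.90 ± 0.63) and Spib (-1.64 ± 0.57), the integrin gene Itga4 (-1.65 ± 0.53) and Ccr6 (-1.60 ± 0.57), together with Dlgap5l2 (-1.87 ± 0.52). Leaving out 1 array at a time ended the calls of Cxcr4 and Itga4 in 8 of 17 runs, P2ry10 in 9, Ikzf1 and Ikzf3 in 11, and Spib and Ccr6 in 12 (highest adjusted p from 0.0813 to 0.122), and with the lymphoid level as a covariate 33 genes fell and 390 rose.

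Epithelial lists were shifted up in HAMSB against HAMS. Each list said to pass did so with the preset correlation and not with an estimated correlation (adjusted p = 0.615). Of 19 goblet cell genes 9 rose and 10 did not pass, with 14 higher adjusted over the list alone, as for Agr2 (0.91 ± 0.21) and the mucin gene Muc1 (0.74 ± 0.17; list median 0.38, adjusted p = 0.000109). Of 21 absorptive colonocyte genes 9 rose and 12 did not pass, with 12 higher adjusted over the list alone, including Guca2b (0.99 ± 0.20) and Guca2a (0.73 ± 0.18; list adjusted p = 0.000619). Of 14 enteroendocrine and tuft cell genes 7 rose and 7 did not pass, with 8 higher adjusted over the list alone. Chgb (0.68 ± 0.13), the somatostatin gene Sst (0.54 ± 0.14) and Chga (0.50 ± 0.10) were among them (list adjusted p = 0.00104). In ion and water transport 6 of 23 rose and 17 did not pass, with 11 higher adjusted over the list alone, as for Hsd11b2 (0.63 ± 0.14) and the potassium channel gene Kcnq1 (0.61 ± 0.14; list adjusted p = 0.00658). Of 15 crypt stem cell and Wnt target genes 4 rose, with 7 higher adjusted over the list alone, including Lgr5 (0.73 ± 0.22) and Ephb2 (0.61 ± 0.16), and that list did not pass (adjusted p = 0.132). The lymphoid level, lower by 1.25 in HAMSB than in HAMS, ran against all 5 lists within diets, with r = -0.82 for goblet cells, -0.78 for absorptive colonocytes, -0.89 for enteroendocrine cells, -0.77 for ion and water transport and -0.81 for crypt stem cells (-0.88 to -0.80 within diets and name styles). Enteroendocrine cells passed with name style as a block and the lymphoid level as a covariate (adjusted p = 0.00528), and the calls of goblet cells (0.095), absorptive colonocytes (0.156) and ion and water transport (0.352) ended.

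Lists of mitochondrial and detoxifying genes were shifted up in HAMSB against HAMS. Of 34 oxidative phosphorylation genes 17 rose and 17 did not pass, with 21 higher adjusted over the list alone, among them Cox7b (0.97 ± 0.22) and the cytochrome c gene Cycs (0.74 ± 0.18; list median 0.37, adjusted p = 2.81e-06). Of 25 genes of fatty acid oxidation and ketogenesis 15 rose and 10 did not pass, with 16 higher adjusted over the list alone, including Ech1 (0.64 ± 0.15) and Cpt2 (0.55 ± 0.15; list median 0.35, adjusted p = 0.000142). Sulphide, ammonia and amino acid handling had 5 rises among 18, with 10 adjusted over the list alone. The sulphide-detoxifying genes Tst (0.82 ± 0.16), Ethe1 (0.67 ± 0.13) and Sqor (0.64 ± 0.17) were among them (list adjusted p = 0.00319). In the xenobiotic list 5 of 18 rose, with 9 adjusted over the list alone, including Akr1b8 (1.03 ± 0.20) and Gclm of glutathione synthesis (0.53 ± 0.14; list adjusted p = 0.00818). All 4 lists had an adjusted p of 0.615 with an estimated correlation, and ran against the lymphoid level within diets (r = -0.81 for oxidative phosphorylation, -0.84 for fatty acid oxidation, -0.88 for sulphide handling and -0.85 for the xenobiotic response), which was lower by 1.25 in HAMSB. Oxidative phosphorylation passed with name style as a block and the lymphoid level as a covariate (adjusted p = 0.00259), and the calls of fatty acid oxidation (0.095), sulphide handling (0.276) and the xenobiotic response (0.259) ended. The gluconeogenic gene Pck1 (1.12 ± 0.21) and the clock gene Per3 (0.64 ± 0.12) rose as well.

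Stromal lists were shifted up and lymphoid lists down in HAMSB against HAMS. Of 20 smooth muscle genes 7 rose, with 14 adjusted over the list alone, as for Myocd (0.48 ± 0.12; list adjusted p = 0.000109), and of 19 fibroblast and matrix genes 8 rose, with 9 adjusted over the list alone, as for Dcn (0.58 ± 0.16; list adjusted p = 0.0038). The mean lymphoid level of the HAMSB arrays differed from that of the HAMS arrays by -1.25. The lists of B cells and germinal centres (median -1.42, adjusted p = 2.59e-06), T and NK cells (median -0.98, adjusted p = 3.89e-05), MHC class II presentation (median -0.61, adjusted p = 0.000619) and the interferon response (median -0.13, adjusted p = 0.0194) were shifted down. Each of these 6 lists had an adjusted p of 0.615 with an estimated correlation. Within diets the lymphoid level correlated with smooth muscle at r = -0.67 and with fibroblasts at -0.71, and with name style as a block and the lymphoid level as a covariate smooth muscle passed (adjusted p = 0.0132) and fibroblasts (0.352) and the interferon response (0.241) did not. Of 16 B cell genes 3 fell, Spib and Ccr7 (-1.19 ± 0.42) among them, and 10 were lower adjusted over the list alone. Of 17 T and NK cell genes Zap70 (-0.88 ± 0.29) and Cd4 (-0.64 ± 0.21) fell and Thy1 (0.51 ± 0.15) rose, with 12 lower and 1 higher adjusted over the list alone. RT1-DOb (-1.42 ± 0.44) was the only fall among 11 MHC class II genes, with 7 lower and 1 higher adjusted over the list alone. Of 25 interferon genes 1 rose by either adjustment. The ribosomal list moved by a median of only -0.03 (1 fall among 42 by either adjustment, adjusted p = 0.0311; adjusted p = 0.676 with an estimated correlation). In DNA repair, Ung rose (0.43 ± 0.10, adjusted p = 0.00607) and Tdg fell (-0.36 ± 0.11), 1 rise and 2 falls among 22 by either adjustment, with a list adjusted p of 0.132. The replication licensing inhibitor gene Gmnn rose by 0.38 ± 0.12 (adjusted p = 0.0229).

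In HAMSB minus HAMS, name style as a block gave 3334 genes (2118 higher, 1216 lower), which held 1670 of the 1821. Within 1 name style (5 against 8 arrays) 2393 genes passed. There the lymphoid level differed by -1.66, against -1.25 over all arrays, so the restriction widened that difference. The block together with the lymphoid level as a covariate left far fewer genes than the block alone, as given under the dependence on processing. With the lymphoid level as a covariate 423 genes passed, Retnlb among them (2.89, adjusted p = 0.00672), and calls that ended included those of Cxcr4 (-0.69, adjusted p = 0.0526), Slc9a3 (0.73, adjusted p = 0.162) and Ung (0.32, adjusted p = 0.0518); Retnlb, Retnla and Retnlg are related genes, and cross-hybridisation between their probe sets was not examined. Leaving out 1 array at a time gave 923 genes (without HAMS replicate 2) to 2868 (without HAMS replicate 1), and besides the 7 calls named above it ended those of Ccr7 in 12 of 17 runs (highest adjusted p = 0.123), Zap70 in 10, Cd4 in 7, Gmnn in 4, RT1-DOb in 3 and Thy1 in 2, and of Lgr5, Slc9a3 and Tdg without HAMS replicate 2. Of 36 lists 15 passed, 15 with the block (14 of them shared), 17 with fry, and 5 with the block and the lymphoid level, where ribosomal proteins turned upward (adjusted p = 0.0491). Array weights gave 3791 genes.

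**Figure D3:**
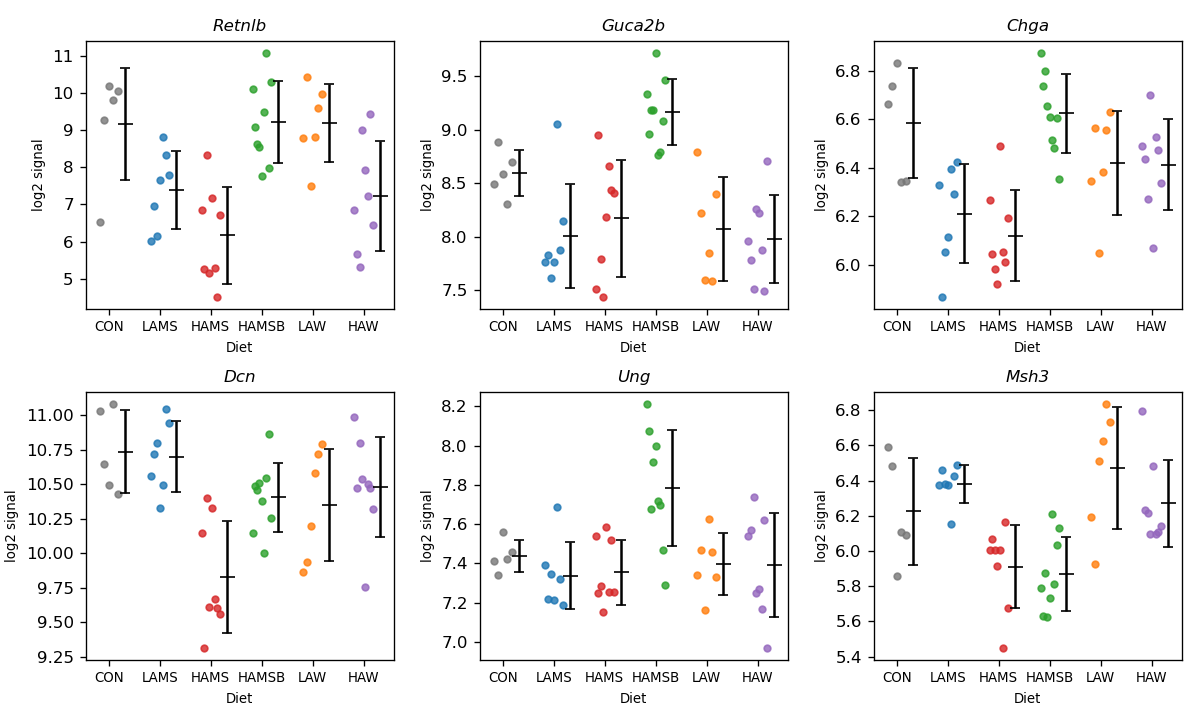
Log2 signal of Retnlb, Guca2b, Chga, Dcn, Ung and Msh3 by diet, with each point an array and bars for the mean ± SD. Retnlb was lowest in HAMS (6.17), and Guca2b and Ung were highest in HAMSB (9.17 and 7.78).

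**Figure D4:**
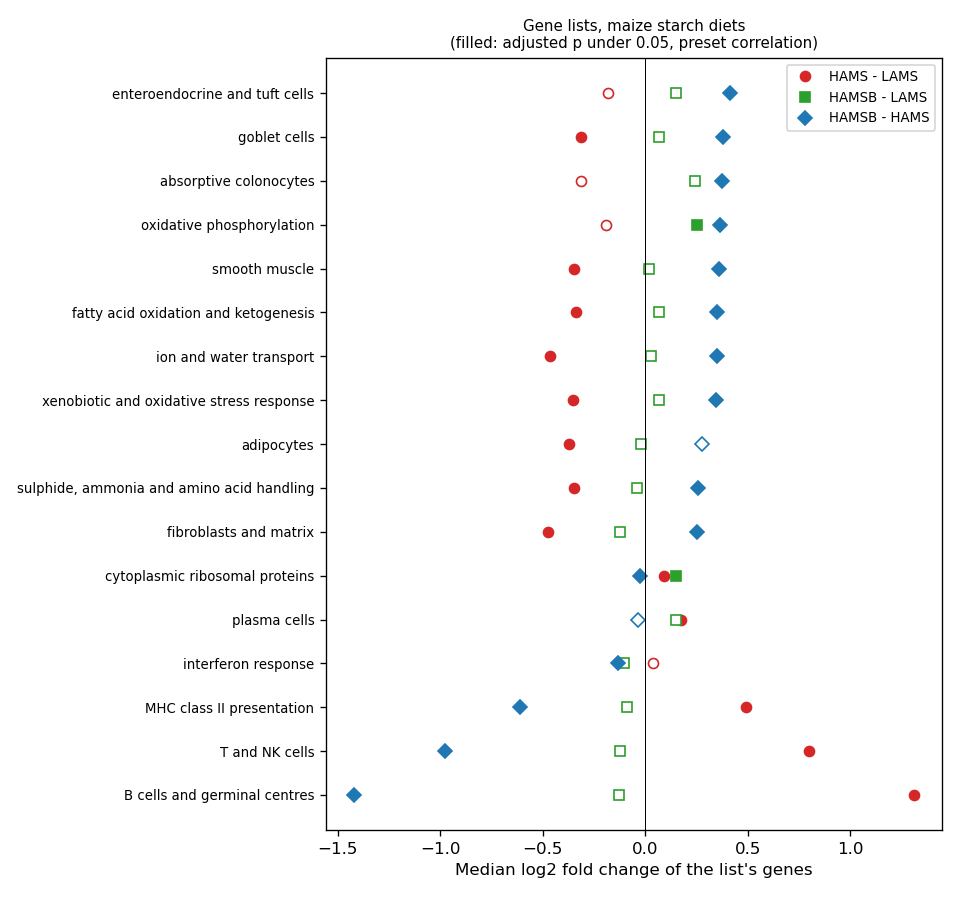
Median log2 difference of each gene list (horizontal axis) in the 3 maize starch comparisons, with filled symbols for lists past an adjusted p of 0.05 with the preset correlation, none of which passed with an estimated correlation. The B cell and germinal centre list lay at 1.31 in HAMS minus LAMS and at -1.42 in HAMSB minus HAMS.

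High-amylose against low-amylose wheat (HAW minus LAW) gave no gene past the test with limma, and 212 genes had an unadjusted p under 0.05. That is fewer than the share of about 0.05 of the 10934 genes that would lie there with no change. Of the 10 genes with the smallest p, Retnlb lay lower in HAW (n = 8) than in LAW (n = 6), at -1.96 ± 0.64, and the calcium-binding protein gene S100g lay higher, at 1.02 ± 0.34. Efhd1 (0.41 ± 0.10), Sgpp1 (0.36 ± 0.11), Ccnq and Hs3st1 were above 0, and Per3 (-0.42 ± 0.14), Spaca6, Fntb and Yju2b below, all with an adjusted p of 1. Adipocyte genes were the most shifted of 9 lists that passed (median 0.29, adjusted p = 1.34e-08; adjusted p = 0.321 with an estimated correlation), with 14 of 15 members above 0, none past the test by either adjustment, and Adipoq at 0.96 ± 0.52. Genes of double-strand break repair were shifted down (median -0.17, adjusted p = 1.48e-05; adjusted p = 0.329 with an estimated correlation), as were cell cycle genes (median -0.13, adjusted p = 0.00752; adjusted p = 0.754 with an estimated correlation). The other 6 lists had medians of 0.05 to 0.12, with an adjusted p from 0.193 to 0.895 with an estimated correlation, and no member passed by either adjustment. The median 95% interval of a gene, before any adjustment, reached 0.26 to either side. The block by name style left 0 genes with limma and 5 of the 9 lists, and fry 0 lists.

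Wheat against maize at low amylose (LAW minus LAMS) gave no gene past the test with limma, and 192 had an unadjusted p under 0.05. Here too this is fewer than the share of about 0.05 of the 10934 genes that would lie there with no change. The 10 genes with the smallest p included Per3, higher in LAW (n = 6) than in LAMS (n = 7) at 0.43 ± 0.14, and RT1-M6-2 at -0.48 ± 0.14. Zcchc10, Marchf2, Abracl, Mtrf1l, Rab12, Med10, Hebp1 and Ddx25 lay between -0.36 and -0.30, all with an adjusted p of 1. Double-strand break repair genes were shifted up (median 0.17, adjusted p = 5.19e-05) and oxidative phosphorylation genes down (median -0.09, adjusted p = 0.00213), both with an adjusted p of 0.982 with an estimated correlation and no member past the test by either adjustment. With name style as a block 0 genes passed with limma, and the median of the latter list was -0.01 (adjusted p = 0.886). With fry 0 lists passed. The LAW mean of Ddx25 (4.46) lay under the low-signal floor of 4.75.

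The mean of both wheats against the mean of LAMS and HAMS gave no gene past the test with limma, and 1802 had an unadjusted p under 0.05. The calcium-activated chloride channel regulator gene Clca1, a goblet cell product, had the smallest p (0.34 ± 0.07, adjusted p = 0.137). Scin (0.71 ± 0.17), Entpd5 (0.52 ± 0.12), Gna14 (0.47 ± 0.11), the muscarinic receptor gene Chrm3 (0.45 ± 0.11), Polr3c and Tox lay higher with wheat, and RT1-M6-2 (-0.38 ± 0.09), Scn4a and Ddx25 lower, the last 2 with both wheat means under the low-signal floor of 4.75, each with an adjusted p of 0.195. Of 12 lists that passed, 8 upward, goblet cell genes had a median of 0.19 (adjusted p = 0.000861) and adipocyte genes of 0.29 (adjusted p = 0.000861), with 5 and 3 members higher adjusted over the list alone. Retnlb was at 1.43 ± 0.44 and Pck1 at 0.56 ± 0.16. B cell genes had a median of -0.61 (adjusted p = 0.000272), T and NK cell genes -0.36 (adjusted p = 0.00467), MHC class II genes -0.27 (adjusted p = 0.00356) and ribosomal protein genes -0.11 (adjusted p = 2.02e-10). Circadian clock genes had a median of 0.17 (adjusted p = 0.007), with 2 higher adjusted over the list alone. Double-strand break repair, fatty acid oxidation, sulphide handling, xenobiotic response and fibroblast genes had medians of 0.14 to 0.17, with 1 fibroblast gene higher adjusted over the list alone. With an estimated correlation no list passed, the smallest adjusted p being 0.664. The median of double-strand break repair (0.15, adjusted p = 0.0252) was 0.00 with name style as a block (adjusted p = 0.961). With the block 0 genes passed, and 0 within 1 name style, where LAW has 1 array, taken to vary like the other diets. The count of genes was 188 without HAW replicate 8, 1 without HAMS replicate 1 or LAW replicate 2, and 2 without HAMS replicate 8. Array weights gave 3086 genes, 2277 higher and 809 lower with wheat. Of the lists 16 passed with name style as a block, 9 of them among the 12, 0 with fry, and 6 with the block and the lymphoid level.

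The amylose effect differed between wheat and maize for 3 genes, tested as HAW minus LAW less HAMS minus LAMS. Eif2s2, a subunit of translation initiation factor eIF2, differed by 1.24 ± 0.20 (adjusted p = 0.00182). Its means were 8.85 ± 0.21 in HAW and 8.54 ± 0.21 in LAW, against 8.02 ± 0.32 in HAMS and 8.95 ± 0.21 in LAMS. Ccdc107 (-2.00 ± 0.38) and Rpph1 (-1.19 ± 0.22) differed the other way, both with an adjusted p of 0.0139. Lsm4 (-0.65 ± 0.14, adjusted p = 0.0751), Rdh14, Ptn, Slc25a23, H3f3b, Mgat2 and LOC366310 had the next smallest p without passing. Of 15 lists that passed, fibroblast and matrix genes had 10 of 19 members higher adjusted over the list alone (median 0.45, adjusted p = 2.08e-06, Dcn at 1.00 ± 0.24). Sulphide, ammonia and amino acid handling had 7 of 18 (median 0.42, adjusted p = 4.26e-05) and adipocytes 5 of 15 (median 0.71, adjusted p = 1.22e-05, Adipoq at 2.21 ± 0.72). B cell genes had a median of -1.42 (adjusted p = 9.63e-06). The lymphoid level, their mean, differed by 1.17 in HAMS minus LAMS and by -0.15 in HAW minus LAW. Within diets it correlated with fibroblasts at r = -0.71, with sulphide handling at -0.88 and with adipocytes at -0.58. With an estimated correlation no list passed, the smallest adjusted p being 0.656. With name style as a block 50 genes passed, 38 of them upward, and all 3 genes were among them. Within 1 name style, where LAW has 1 array, taken to vary like the other diets, 0 genes passed with limma, and Eif2s2 was at 1.52 (adjusted p = 0.124), Rpph1 at -1.59 (0.0793) and Ccdc107 at -1.68 (0.536). Without LAW replicate 2 the count was 1, with Ccdc107 and Rpph1 at an adjusted p of 0.0573, without HAW replicate 8 it was 219, and without 1 of 7 other arrays it was 5 to 17, while array weights gave 1119 genes, the 3 among them. With fry 0 lists passed (smallest adjusted p = 0.0573), and 8 with the block and the lymphoid level.

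Whether the starches opposed the LAMS minus CON difference was tested over genes, which are not independent replicates, with the LAMS arrays divided so that both sides shared none. The correlation over genes was 0.22 for HAMS minus LAMS, where 95% of 100 permutations of the residuals over arrays gave -0.52 to 0.38 (permutation p = 0.129 for the covariance). For HAMSB minus LAMS it was -0.12 (-0.51 to 0.39, permutation p = 0.723) and for HAW minus LAW -0.11 (-0.72 to 0.63, permutation p = 0.762). With name style as a block the 3 correlations were 0.32 (permutation p = 0.0594), -0.45 (0.129) and -0.03 (0.941). Every permutation p lay above 0.05 and every correlation within the range the permutations gave. This also held with no low-signal filter and with the range of the animal numbers as a block. The permutation p ignores the sign of the covariance, while permutations of the maize comparisons reached further below 0 than above it. The covariance of HAMS minus LAMS with name style as a block, 0.0313, lay above the 95% range of its permutations (-0.034 to 0.0248). It also lay above with no low-signal filter (0.0177, -0.0374 to 0.0151) and with the animal number block (0.0169, -0.0519 to 0.0153). In the main model it did not (0.0176, -0.0327 to 0.0204). A covariance above 0 is a shift in the same direction as LAMS minus CON, the reverse of opposition. The 7 genes reported here of those fixed beforehand for every comparison (Mdm2, Top1, Msh3, Ung, Gmnn, Parg and Slc16a1) passed only as described above; those that did not pass lay between -0.30 and 0.02 in HAMS minus LAMS (smallest adjusted p = 0.0818), -0.29 and 0.26 in HAMSB minus LAMS (0.0797), and -0.17 and 0.36 in HAMSB minus HAMS (0.0695). All 7 failed to pass in LAMS minus CON (-0.24 to 0.21, smallest adjusted p = 0.636), HAW minus LAW (-0.20 to 0.06), LAW minus LAMS (-0.11 to 0.18), wheat minus maize (-0.08 to 0.23) and the comparison of amylose effects (-0.02 to 0.60).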

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

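Some tests in this part were chosen only after the results were seen. These were the lymphoid level's range within diets and its share in the rises and in the falls of HAMSB minus HAMS taken apart. The values within 1 name style and with the lymphoid level as a covariate were likewise chosen afterwards. The other tests of shares, splits, variation between diets and amylose effects were set before. The search for arrays far from their diet and the test of probe sets with no gene listed were not among them. The genes in that search were taken from those named in the text. The splits of the arrays were drawn a second time, to exclude duplicates, after a first draw had been seen.

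The HAMS minus LAMS change, 1545 genes, stood beside a narrower array spread (by 0.2003, and by 0.118 within 1 name style, where exact permutation p = 0.212), a shared name style and a higher lymphoid level in HAMS. Slopes fitted in other diets predicted 23.7% (95% interval 14.4 to 35.9) of the median signed change from the lymphoid level. That share takes each gene to follow the level in a straight line on the log2 scale, which was not tested. It therefore does not exclude lymphoid tissue as the whole cause. For name style the share was 29.5% (8.44 to 69.1) and for array spread 40.5% (24.4 to 50.7), intervals that reach past 50%, so a batch or a narrower signal range cannot be told apart from the diet as the main source. Each share was estimated alone, not jointly, and its interval leaves out the sampling error of the compared diets. The high-amylose starch stays open as a biological explanation. Of 100 splits of these arrays, the real one included, 2 gave as many genes (highest other 1908), which argues against chance. The splits ignore name style and the lymphoid level, so they do not exclude a chance imbalance in these.

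The HAMSB minus HAMS change, 1821 genes, was predicted to -4.14% (-26.7 to 19.8, from 92 resamplings) by name style and to 7.54% (-9.05 to 16.3) by array spread, which argues against both as the main cause. The lymphoid level predicted 35.2% (29.6 to 42.3) over all genes and 35% (27.7 to 41.3) over the 1550 that rose. These shares too take a straight line on the log2 scale, which was not tested, so they do not exclude lymphoid tissue as the whole cause. With the lymphoid level as a covariate 423 genes passed, 390 higher and 33 lower in HAMSB. The shares also rest on genes picked by their p in this same comparison, which the check on planted genes did not cover. Lymphoid tissue thus stays open as the main source of the rises. Over the 271 genes that fell the share was 37.1% (27.1 to 55). Given the width of this interval and the covariate fit, lymphoid tissue cannot be told apart from the diet as the main source of the falls. Of 100 splits, the real one included, 2 gave as many genes (highest other 2966), which argues against chance. The highest other split parted the lymphoid level by 1.87, so the splits do not exclude a chance imbalance in that level. The butyryl groups stay among the open explanations, untested beyond this contrast.

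The lymphoid level ranged widely within diets, from 2.616 between the lowest and highest array in CON to 3.66 in HAMS. In CON that width rests on replicate 5, and without it the range was 0.263, while without the highest array of each it was 2.23 to 3 in the other 5 diets. The range restates the spread that led to it, so it decides nothing on whether lymphoid follicles were caught in some tissue pieces, and that stays open. A difference between the diets in lymphoid tissue could not be excluded (permutation p = 0.282 for the variation between diets). Of the genes that measure it, 16 of the B cell and germinal centre list were tested, and such cells are also normal residents of the colon wall.

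For the other counts, 2 of 100 splits gave as many genes in HAMSB minus LAMS (741 genes, highest other 1075) and 1 of 100 for any diet (3355 genes, highest other 1235). Only 4 other splits gave any gene in HAMSB minus LAMS and 2 for any diet, so far smaller counts would have had nearly as small a share. These shares argue against chance but do not test the size of the counts. They also do not exclude an uneven fall of name style or the lymphoid level over the diets. For the difference between amylose effects (3 genes, 4 of 100, highest other 263) only 3 other splits gave any gene, so any count above 0 would have had as small a share, and the splits add little to the adjusted p of its genes; 0 genes passed within 1 name style. Where the real split gave 0 genes every split gives as many, so the count of splits decides nothing for LAMS minus CON (100 of 100, highest other 949), HAW minus LAW (100 of 100, highest other 1137), LAW minus LAMS (100 of 100, highest other 108) or wheat minus maize (100 of 100, highest other 3170). Splits that follow no diet and yet call many genes point to a structure of the samples, and how many genes the highest calls depends strongly on which splits are drawn. The highest splits of these 4 comparisons and of the difference between amylose effects parted the lymphoid level by -0.429, 0.652, -1.77, 1.73 and -0.585 in that order, against median absolute differences of 0.425, 0.513, 0.415, 0.413 and 0.453 over the splits. They parted the array spread by -0.0873, 0.243, 0.0314, 0.00699 and 0.279, against 0.0331, 0.084, 0.0455, 0.043 and 0.0867. Those of HAMS minus LAMS, HAMSB minus LAMS and HAMSB minus HAMS parted the lymphoid level by -1.64, -0.707 and 1.87, against 0.464, 0.355 and 0.397, and the spread by 0.0819, -0.113 and -0.115, against 0.073, 0.0351 and 0.0388.

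Some arrays lay far from the others of their diet, 8 among 78 groups of values, where chance marks about 1 in 20 groups. The array spread was 2.95 in HAMSB replicate 5 (next 3.07) and 2.678 in HAW replicate 8 (next 3.12), each the lowest of its diet. The lymphoid level was 8.368 in CON replicate 5 (next 6.02). LAMS replicate 5 had a Guca2b level of 9.051, a Ung level of 7.686 and a Msh3 level of 6.155. Retnlb was at 6.54 in CON replicate 1 (next 9.28), and Cspg5 at 4.428 in HAMSB replicate 9 (next 4.92).

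The amylose effect differed between wheat and maize, by a test of the difference itself, for Eif2s2 (1.243), Rpph1 (-1.189) and Ccdc107 (-2.003). It differed, by the list test with the preset correlation, for list medians of fatty acid oxidation (0.355), sulphide, ammonia and amino acid handling (0.416), the xenobiotic response (0.445), ion and water transport (0.516), oxidative phosphorylation (0.242), absorptive colonocytes (0.372), goblet cells (0.347), smooth muscle (0.279), adipocytes (0.709) and fibroblasts (0.448). Medians below 0 were those of the interferon response (-0.107), MHC class II (-0.58), ribosomal proteins (-0.131), T and NK cells (-0.975) and B cells and germinal centres (-1.42). With an estimated correlation the smallest adjusted p among these lists was 0.656. Within diets the lists above 0 ran against the lymphoid level (r from -0.88 to -0.576) and those below 0 ran with it (0.529 to 1). That level differed by 1.17 in HAMS minus LAMS and by -0.15 in HAW minus LAW. For the lists, an uneven lymphoid level thus cannot be told apart from a difference between the grains.

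Of 13581 probe sets with no gene listed, a signal outside the tested genes, 7356 reached the low-signal floor, and adjusted over these alone 6 changed in LAMS minus CON, 3 up and 3 down. With all probe sets of the table adjusted together 0 passed in that comparison with limma.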

How the results depend on the processing

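The alternatives with array spread or the lymphoid level as a covariate, with name style and the lymphoid level together, without the 2 arrays of lowest spread, and within 1 name style were chosen after seeing the data; all others were planned. Over all alternatives except left-out arrays, 99 counts stayed within 1.5 times the value and 43 moved. Of the list results 357 kept direction and side of the threshold, 162 lost the threshold and 6 turned direction, and of the named gene results 2401 kept both, 332 lost the threshold, 83 gained it and 0 turned. The 9 opposition results kept theirs. Unless said otherwise, the cause was not tested. Genes near the low-signal floor of 4.75 are limited by signal over background, and the filters change which of them are tested.

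Testing all probe sets, which adds features and leaves out the low-signal filter, gave 2643 in HAMS minus LAMS, 1 in wheat minus maize, 9 for the difference between amylose effects (below, the interaction) and 5744 for any diet. Array weights gave 234 in LAMS minus CON, 4059 in HAMS minus LAMS, 3724 in HAMSB minus LAMS, 3791 in HAMSB minus HAMS, 3086 in wheat minus maize, 1119 for the interaction and 7524 for any diet. Fitting only the compared diets, which leaves fewer arrays, gave 492 in HAMS minus LAMS, 483 of them shared. Name style as a block gave 36 in LAMS minus CON, 945 in HAMS minus LAMS, 327 in HAMSB minus LAMS, 3334 in HAMSB minus HAMS, 50 for the interaction and 1398 for any diet. Name style with the range of the animal numbers gave 8, 901 and 159 in the comparisons of LAMS minus CON, HAMS minus LAMS and HAMSB minus LAMS, 33 for the interaction and 491 for any diet. The replicate block gave 2 in LAMS minus CON and 602 in HAMS minus LAMS, 600 of them shared.

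Array spread as a covariate gave 3 in LAMS minus CON, 6 in HAMS minus LAMS and 1533 for any diet. The lymphoid level as a covariate gave 11 in LAMS minus CON, 575 in HAMS minus LAMS, 1621 in HAMSB minus LAMS, 423 in HAMSB minus HAMS, 3 in wheat minus maize and 5 for the interaction. With name style as well it gave 120 in LAMS minus CON, 99 in HAMS minus LAMS, 616 in HAMSB minus HAMS, 30 for the interaction and 598 for any diet. Without the 2 arrays of lowest spread HAMSB minus LAMS gave 1131 and the interaction 6. Within 1 name style HAMSB minus LAMS gave 38 and the interaction 0, the latter from a fit with 1 LAW array, assumed to vary like the other diets. List medians that turned were small: ribosomal proteins in HAMSB minus LAMS by the test's direction, at 0.008364 with name style as a block; oxidative phosphorylation in HAMSB minus LAMS at -0.01092 with both blocks and in HAW minus LAW at -0.01305 with name style and -0.02604 with both; and double-strand break repair in wheat minus maize at 0.002756 (by the test's direction) and -0.01165.

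Leaving out each array in turn gave 0 to 3 genes in LAMS minus CON, 614 to 2425 in HAMS minus LAMS, 158 to 1384 in HAMSB minus LAMS and 923 to 2868 in HAMSB minus HAMS. It gave 0 to 0 in HAW minus LAW and in LAW minus LAMS, 0 to 188 in wheat minus maize, 1 to 219 for the interaction and 2513 to 4334 for any diet. In LAMS minus CON the count was 1 without CON replicate 1, 3 without CON replicate 2 or LAMS replicate 5, and 2 without LAMS replicate 7. In HAMS minus LAMS it was 749 without LAMS replicate 3, 614 without LAMS replicate 6, 2425 without HAMS replicate 1, 906 without replicate 2, 959 without replicate 4, 642 without replicate 6 and 766 without replicate 8 of HAMS. In HAMSB minus LAMS it was 1384, 158, 216, 197 and 293 without LAMS replicates 1, 2, 3, 4 and 6, and 368, 292, 424, 456, 202 and 1272 without HAMSB replicates 1, 2, 3, 4, 5 and 9. In HAMSB minus HAMS it was 2868, 923 and 1053 without HAMS replicates 1, 2 and 4, and 2734 without HAMSB replicate 9. In wheat minus maize it was 1 without HAMS replicate 1, 2 without HAMS replicate 8, 1 without LAW replicate 2 and 188 without HAW replicate 8. For the interaction it was 5 and 8 without LAMS replicates 1 and 2, 16, 11 and 17 without HAMS replicates 1, 3 and 5, 1 and 10 without LAW replicates 2 and 6, and 9 and 219 without HAW replicates 5 and 8. Of 179 named gene results, 48 lost their call in at least 1 such run and 0 changed sign. Replicate numbers do not pair the arrays: the median correlation of residuals was -0.053 over 94 same-numbered pairs and 0.02 over 671 others.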

Other observations

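The list tests in this part were planned, and no test was added after its result was seen. Of 8 plasma cell genes 2 rose in HAMSB against LAMS by either adjustment, while the list did not pass (adjusted p = 0.178). Of 15 circadian clock genes 4 rose in HAMSB against HAMS by either adjustment (median 0.19, list adjusted p = 0.0542), and 3 fell in HAMS against LAMS by either adjustment (median -0.28, list adjusted p = 0.0922). In the list of p53 targets and damage signalling, 4 of 22 genes rose in HAMSB against HAMS (adjusted over the list alone, 4 higher and 1 lower), with a median of 0.00 and a list adjusted p of 0.585. Of 16 genes of epithelial antimicrobial defence 2 rose and 2 fell in HAMS against LAMS (adjusted over the list alone, 2 higher and 3 lower), with a list adjusted p of 0.955. Adipocyte genes had a median of 0.28 in HAMSB against HAMS, with 4 of 15 higher by either adjustment (list adjusted p = 0.0594).

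Among the 7356 probe sets with no gene listed that reached the low-signal floor, adjusted over these alone, 919 changed in HAMS minus LAMS, 457 in HAMSB minus LAMS, 481 in HAMSB minus HAMS, 10 in wheat minus maize and 25 in the difference between amylose effects, and 0 in HAW minus LAW and LAW minus LAMS. The correlation of any 2 arrays over all probe sets ran from 0.941 to 0.993, so no array was a copy of another. Centring each array shifted no comparison by more than 0.06 (0.055 for the difference between amylose effects).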
